A study of Homo sapiens with 5 samples.

How the data were processed

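Gene expression was measured on 5 Illumina bead arrays, each hybridised with biotinylated cRNA from total RNA of human mobilized CD34+ cells, which are blood stem and progenitor cells. Per the labels, the cells were stably infected with viruses that express either a scrambled control shRNA or an shRNA against DPY30, and were harvested on day 0 or on day 9 of culture in medium with SCF, FLT-3 ligand, IL-3, IL-6, GM-CSF and G-CSF. Control cells were measured on 1 array at day 0 and 1 array at day 9. Knockdown cells were measured on 2 arrays at day 0, 1 with shRNA 2 and 1 with shRNA 5, and on 1 array at day 9, with shRNA 2. The labels do not state whether the cultures came from 1 donor or several, or whether any were separate cultures of the same kind.

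The deposited table of non-normalized values holds an intensity for each of 47322 probes on each array, on a linear scale, without background subtraction or scaling between arrays. Beside each intensity the table gives a detection p-value, per the file headers. The authors' processed table lists 24981 probes as intensity values. Checked against the first table, it holds the probes with a detection p-value under 0.05 on at least 1 array, with each array multiplied by 1 factor that equalises the array medians. The scanner software and the tool used for scaling are not recorded in the labels or headers.

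From the non-normalized table, the background was estimated from the detection p-values and removed with limma's neqc (normexp with an offset of 16, quantile normalization over all 5 arrays, log2). Probes were named from GEO's platform annotation, with symbols updated through the Entrez identifier. Of the 24981 probes in the authors' table, 18180 had 1 gene, 4 had several and 6797 had none in that annotation. Of the 18184 annotated probes, 18169 matched an identifier, and no symbol had to be updated. Probes with several genes, Y-linked genes and XIST were left out. HLA genes and other genes whose presence or sequence differs between people were not named singly. Probes with a detection p under 0.01 on at least 1 array were kept, and the probe with the highest mean signal stood for its gene, which gave 11655 genes. Probes of near-identical paralogs, such as the alpha defensins, the globin pairs and the histones, cannot be told apart with certainty.

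The 4 groups were fitted together with limma (lmFit, then eBayes with a mean-variance trend, and Benjamini-Hochberg adjustment over the 11655 genes). The pair of day 0 knockdown arrays gives the fit its 1 residual degree of freedom, and the prior added 3.32. Every lone array is therefore assumed to vary as shRNA 2 and shRNA 5 differ from each other. Since the arrays are not stated to be separate cultures, the p-values measure only the spread between these samples. That spread mixes technical variation with differences between the 2 shRNAs, between which 629 genes differed at least 2-fold. It can therefore be larger than the spread between like arrays, which was not measured. The contrasts were knockdown against control at day 0 and at day 9, day 9 against day 0 in the control and in the knockdown, and the interaction of knockdown and day. In the knockdown over time and in the interaction, day 0 holds shRNA 2 and shRNA 5 while day 9 holds shRNA 2 alone. The shRNA is therefore mixed with the day in both. A gene was called at an adjusted p under 0.05. Beside the calls, genes that differed at least 2-fold were counted without a test. At day 0 both shRNAs had to show this in the same direction, and a gene had to be detected on at least 1 of the arrays compared. Comparisons of 1 array against 1 have no replicate check.

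In all, 24 gene lists were fixed from general knowledge of blood cells before the data were examined. They cover the SET1/MLL complex, HOX and MEIS genes, stem and progenitor genes, the primary granule, neutrophil maturation, monocytes and macrophages, dendritic cells with MHC class II, erythroid cells, megakaryocytes and platelets, mast cells with basophils and eosinophils, lymphoid cells, the G1/S and the G2/M cell cycle, CDK inhibitors and p53 targets, MYC and ribosome biogenesis, the interferon response, inflammatory cytokines and chemokines, unfolded protein and amino acid stress, immediate early and heat shock genes, cholesterol and lipid synthesis, oxidative phosphorylation, ribosomal proteins, core histones, and myeloid transcription factors. The lists hold 612 genes in all, 18 of them in several lists. For each list the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list counted as outside the random range below percentile 2.5 or above its mirror image at the upper end. This describes the arrays and is not a p-value. At day 0, camera was also run with its preset correlation of 0.01 and with an estimated correlation.

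The genes named in the text were chosen by a rule fixed at the same stage. For the comparisons of knockdown with control and of the control over time it took the 12 genes with the largest difference each way among genes detected on every array compared, ranked at day 0 by the smaller of the differences with shRNA 2 and shRNA 5. For the knockdown over time and the interaction it took 6 each way. A further 4 each way were detected on every array of one side and none of the other, and their fold is given as a lower bound at the dimmest signal called detected. DPY30, every SET1/MLL complex member and up to 4 members of each list with the largest difference were added. Genes called over a list alone that fall outside this rule (HBG2 at day 0, LYZ) were named after their values were seen.

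The fit and the list percentiles were tested on simulated data with 200 genes changed in each of 20 runs. Of genes changed by 2 on the log2 scale, the test called 18.2% for knockdown at day 0, 6.55% for the control over time, 7.55% for knockdown at day 9 and 17.2% for the knockdown over time. At a change of 4 it called 90.4%, 80.5%, 77.7% and 91.3%. In these runs 210 unchanged genes per run passed the 2-fold rule at day 0 and 627 at day 9. Lists shifted by 0.5 were outside the random range in 100% of cases, and unshifted lists in 2% for knockdown at day 0, 4% for the control over time, 12% for knockdown at day 9 and 6% for the knockdown over time.

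Alternatives were quantile normalization without background correction, median scaling in place of quantiles, an offset of 50, the authors' values, other detection filters, the mean of a gene's probes, eBayes without a trend or with robust settings, an additive fit, a fit of day blocked on the shRNA, other fold thresholds, and leaving out each day 0 knockdown array. Analyses used R 4.3.3, limma 3.58.1 and matrixStats 1.5.0. Plots used Python 3.11.15 and matplotlib 3.10.9. Between 16216 and 17703 of the 47322 probes were detected per array, and the median intensity of all probes was 71.5 to 75.8 against a background of 60.2 to 63.9. The number of arrays limits the precision of every value.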

Results

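DPY30 is a shared core subunit of the SET1/MLL complexes, which methylate lysine 4 of histone H3 at active genes. The arrays address how its loss alters expression in human CD34+ cells before and after culture in medium that drives myeloid and monocytic differentiation. DPY30 signal was lower than in the scrambled control by −2.72 (log2) with shRNA 2 and −2.39 with shRNA 5 at day 0, and was 3.99-fold lower with shRNA 2 at day 9. On the log2 scale its level was 11.33 in the control at day 0, 8.61 with shRNA 2 and 8.94 with shRNA 5, and at day 9 it was 10.21 in the control and 8.21 with shRNA 2. The mean difference at day 0 was −2.55 (SE 0.28), with an adjusted p = 0.0116 from limma over the 20 members of the SET1/MLL complex list alone, while over all 11655 genes it was not called. In the control, DPY30 itself was lower at day 9 than at day 0 by −1.12 (limma adjusted p = 0.124).

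The catalytic and scaffold partners of DPY30 showed smaller differences. WDR5, a scaffold of every complex of this family, was higher by 0.65 with shRNA 2 and lower by −0.40 with shRNA 5. RBBP5 was at −0.49 and the adaptor PAXIP1 at −0.50 with shRNA 5, but their means over both shRNAs were −0.19 and −0.33. At day 9 ASH2L, which binds DPY30 directly, was at 0.45 and the methyltransferase SETD1B at 0.50. The list's median was −0.09 with shRNA 2, −0.20 with shRNA 5, below the range of random lists, and 0.14 at day 9. At day 0, 11 of the 20 members were lower and 3 were higher with both shRNAs, and at day 9, 14 were higher and 6 lower.

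**Figure D1:**
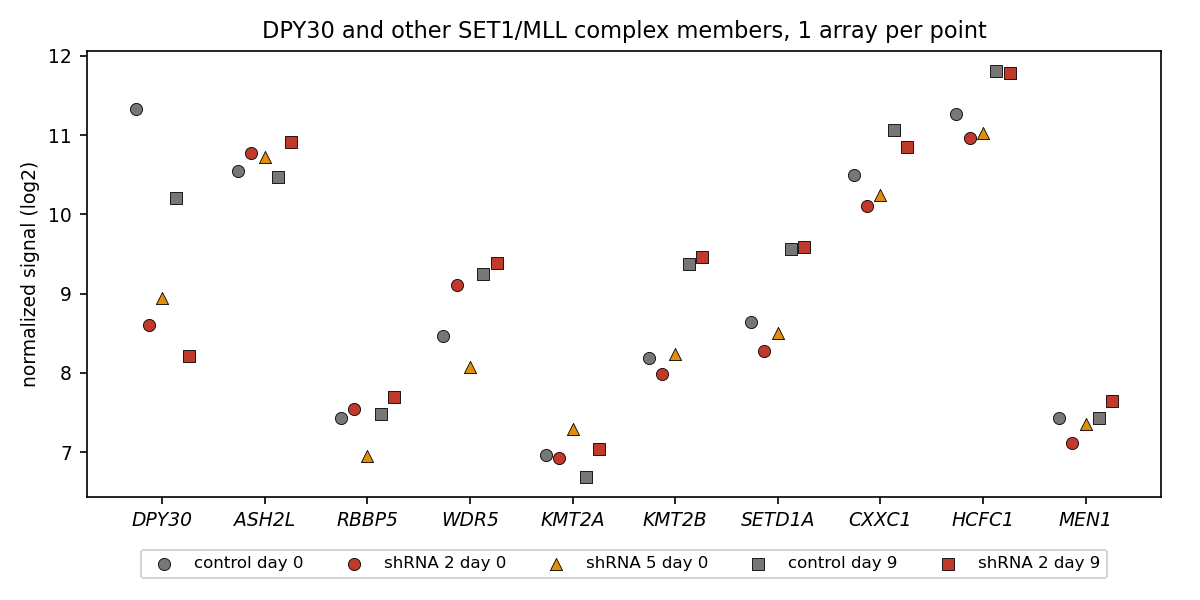
Normalized log2 signal of DPY30 and of other SET1/MLL complex members on each of the 5 arrays. Each point is 1 array, with circles and triangles for day 0 and squares for day 9.

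At day 0, before differentiation, the knockdown cells carried more transcripts of the megakaryocyte, platelet and red cell lineages than the control. The adult alpha globin gene HBA1 was higher by 4.29 with shRNA 2 and 2.18 with shRNA 5 (mean 3.23, SE 0.91), and its near-identical paralog HBA2 by 3.94 and 2.15. The fetal globin gene HBG1 was higher by 1.63 and 1.77 (mean 1.70, SE 0.19). Of the 24 megakaryocyte and platelet genes, 21 were higher and 1 was lower with both shRNAs, among them the surface receptors TREML1 (2.18 and 0.69), GP6 (1.26 and 0.91) and CD9 (1.71 and 0.49, although its dimmer probe went the opposite way). The list's median was 1.08 with shRNA 2 and 0.40 with shRNA 5. For the 24 erythroid genes the medians were 0.85 and 0.40, with 15 higher and 2 lower with both.

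Several progenitor markers were lower. DNTT, the terminal transferase of early lymphoid cells, was lower by −1.93 with shRNA 2 and −1.25 with shRNA 5, and the cyclin gene CCND2 by −1.06 and −0.96. Of the 35 stem and progenitor genes 18 were lower and 7 higher with both shRNAs (median −0.28), including the cytokine receptor FLT3 (−1.29 and −0.50), NPR3 (−1.56 and −0.78) and SMIM24 (−1.30 and −0.47). The list's median was −0.45 with shRNA 2, below the range of random lists, and −0.11 with shRNA 5, within it. The primary granule list, which holds proteases of promyelocytes and other granulocyte genes, had a median of −0.38. Of its 17 members 13 were lower and 1 higher with both shRNAs. Among the lower were CTSG (−1.09 and −0.89) and CEACAM8 (−0.77 and −0.83). The lymphoid list of 8 genes was mixed, with 4 lower and 3 higher with both shRNAs, a median of −0.26 and a mean of −0.01. CD79B, part of the B cell receptor, was lower by −0.95 and −0.74, while the cytotoxic protease gene GZMB was higher by 1.57 and 1.44. With either shRNA alone (−0.26 and −0.10) the list lay within the random range, and its median was 0.01 when the detection filter was removed, with more members. Myeloid transcription factors had a median of −0.17, with 13 of 29 lower and 6 higher, among them GFI1 (−0.89 and −0.50) and IRF8 (−1.19 and −0.30). That list was below the random range with shRNA 2 (−0.27) and within it with shRNA 5 (−0.04), and the median of both left the range in 3 of 8 other settings.

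Proliferation genes were lower as well. None of the 40 G1/S genes was higher with both shRNAs and 31 were lower (median −0.45), including the replication helicase subunits MCM2 (−0.67 and −0.99) and MCM4 (−0.87 and −0.79) and UNG, which removes uracil from DNA (−0.58 and −1.33). Of the 41 G2/M genes 32 were lower and 2 higher (median −0.36), with the list below the random range for shRNA 5 (−0.55) and within it for shRNA 2 (−0.15). The MYC and ribosome biogenesis list had 27 of 40 members lower and 3 higher (median −0.28), with the nucleolar helicase gene DDX21 at −0.79 and −0.44, while ODC1 was higher by 0.67 and 0.56. Core histone genes went the other way, with 10 of 14 higher and 1 lower (median 0.75, and 0.20 among the 11 detected on all 5 arrays), such as H4C8 (1.01 and 1.96) and H2BC5 (1.46 and 0.70), although the probes of related histones cannot be separated with certainty. The cell cycle inhibitors CDKN1A (1.26 and 0.93) and CDKN2D (1.24 and 1.09) were also higher. The 25 CDK inhibitor and p53 target genes together had a median of −0.01, within the random range, and a mean of 0.11.

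Several signalling and monocyte lists differed between the shRNAs, each measured on 1 array, and these differences were not tested. The 38 interferon response genes had a median of 0.78 with shRNA 5, with 36 higher and 2 lower, and −0.04 with shRNA 2. IFIT1, an interferon-induced RNA sensor, was higher by 0.89 with shRNA 2 and 2.79 with shRNA 5, while MX1 was at −0.26 and 2.66. Inflammatory cytokine and chemokine genes had a median of 0.33 with shRNA 5 and −0.03 with shRNA 2, with CCL5 higher with both (2.86 and 1.59). The monocyte and macrophage list was lower with shRNA 2 (−0.65) and higher with shRNA 5 (0.47), although APOE was lower (−1.61 and −0.63) and the scavenger receptor gene CD36 higher (0.78 and 0.93) with both. Dendritic and MHC class II genes were at −0.31 and 0.12. Mast cell, basophil and eosinophil genes were at 0.35 with shRNA 2 and −0.02 with shRNA 5. Immediate early and heat shock genes had a median of 0.19 for both together, with KLF2 higher by 0.69 and 1.76. The median was 0.12 with shRNA 2, within the random range, and 0.17 with shRNA 5, above it. Of the 23 members, 9 went opposite ways between the shRNAs.

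Several lists stayed within the random range at day 0. The HOX and MEIS list, whose genes are classic targets of the MLL complexes, had a median of 0.00 over 11 members, with 5 higher and 3 lower with both shRNAs. Neutrophil maturation was at −0.08 (mean 0.06), with 8 of 20 genes higher and 8 lower, the granule gene LCN2 being higher by 0.94 and 0.90. The medians were −0.05 for unfolded protein and amino acid stress, 0.06 for cholesterol and lipid synthesis, −0.04 for oxidative phosphorylation and −0.08 for ribosomal protein genes.

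In all, 107 genes differed at least 2-fold in the same direction with both shRNAs at day 0, 100 higher and 7 lower, of 11211 detected. The control array detected fewer genes, 10071, than the arrays of shRNA 2 (10655) and shRNA 5 (10646). Detected with both shRNAs and not in the control were 404 genes, against 76 the other way. Among genes detected on every array compared, 71 were higher and 6 lower. Whether the lower detection in the control adds to the skew was not tested. Besides the globin genes, the highest were EHD3, which acts in endosome recycling (2.04 and 2.26), the cilia gene RSPH1 (1.98 and 3.92), the protease gene PCSK6 (2.81 and 1.80), SSX2IP (1.75 and 1.69), RTN1 (2.80 and 1.69), RBPMS2 (2.41 and 1.67), EGF (1.64 and 1.83), PLA2G4C (2.12 and 1.61) and the theta globin gene HBQ1 (2.31 and 1.64). The lowest after DPY30 and DNTT were PXDN (−1.14 and −1.26), the left-right signalling gene CFC1B, which the array cannot separate with certainty from its paralog (−1.11 and −1.12), VANGL2 (−1.05 and −1.11) and CDCA7, a chromatin remodelling cofactor (−1.35 and −1.04). RAB3C was detected with both shRNAs and not in the control and was at least 4.12-fold higher, and so were SYNM at least 4.01-fold, ABLIM3 at least 3.66-fold and HTR2A at least 3.65-fold. In the other direction CXCL13 was at least 2.11-fold lower.

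**Figure D2:**
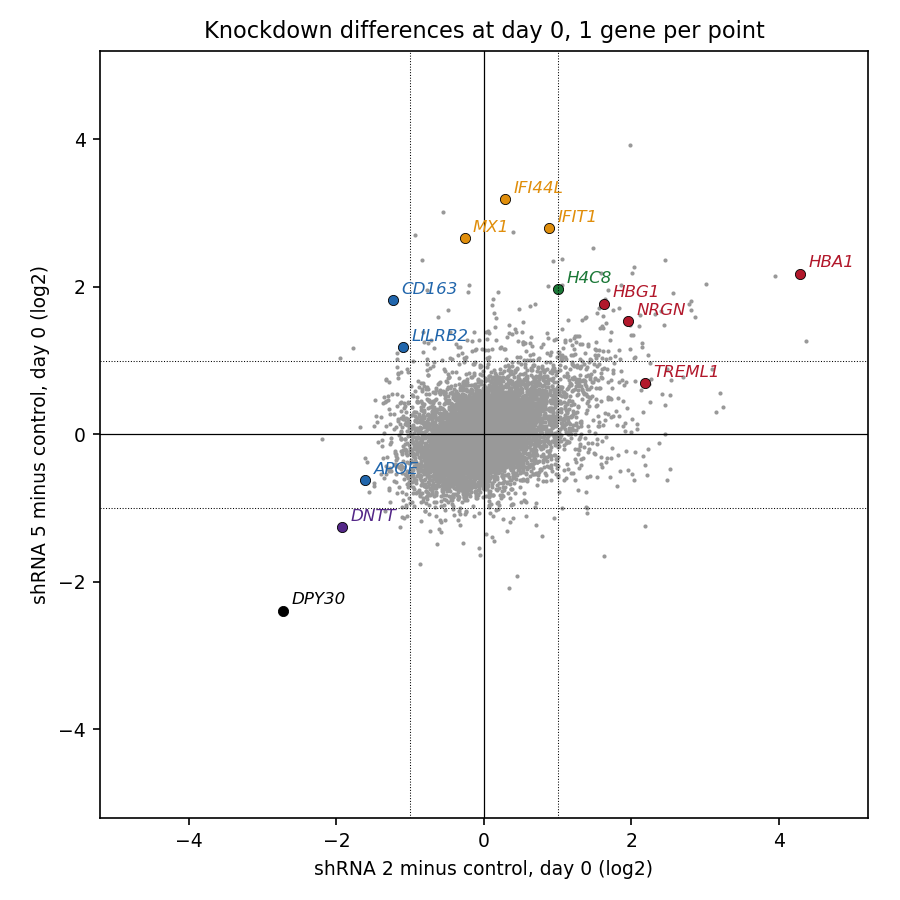
Log2 differences from the control at day 0 with shRNA 2 and with shRNA 5, for each of the 11655 genes detected on at least 1 of the 5 arrays. Both axes share the same control array.

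The count with both shRNAs rests on 1 shared control array. With 639 genes at least 2-fold different with shRNA 2 (468 higher, 171 lower) and 267 with shRNA 5 (209 higher, 58 lower), independent lists would share 8.72 higher and 0.885 lower genes. Simulated unchanged cells measured against 1 shared control gave 25.6 genes higher and 26 lower with both at the moderated spread, and 115 higher and 117 lower at the unmoderated spread. The correlation of the shRNA 2 and shRNA 5 differences was r = 0.386 with a covariance of 0.0759, against simulated values of 0.501 and 0.0746 at the moderated spread and 0.499 and 0.126 at the unmoderated spread. Part or all of the excess of higher genes over independent lists may therefore come from the shared control, while the 7 lower genes are fewer than in either simulation. The self-test, which draws the spread of each gene anew, gave 210 unchanged genes per run past this rule in either direction, among 11655 genes. The observed number was 107 of 11211. Genes are not independent replicates.

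For knockdown against control at day 0, limma called 0 genes over all 11655, with 323 at an unadjusted p under 0.05 where 583 would come by chance. Adjusted over their list alone, DPY30, HBG1 with its paralog HBG2 (adjusted p = 0.00764) and GZMB (adjusted p = 0.0333) were called. Of the 24 lists, 6 lay above and 7 below the range of random lists. If the lists were random draws of genes, 1.2 in all would lie outside. Genes of a fixed list can vary together, unlike those of a random draw. The excess over 1.2 is therefore not a test of knockdown, since any difference between the cultures could move whole lists. With the preset correlation, camera called 14 lists, among them G1/S (adjusted p = 5.51e-13), megakaryocyte and platelet (1.3e-11) and core histone (2.64e-06). All of these calls were lost with an estimated correlation, with adjusted p = 0.706 for G1/S and for megakaryocyte and platelet, and 0.774 for the interferon response. That correlation is estimated from 1 residual degree of freedom, so the loss says little about any list.

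Over 9 days the control cells lost megakaryocyte and stem cell transcripts and gained those of monocytes, macrophages and neutrophils. The platelet chemokine gene PPBP fell by −5.71 (SE 0.22, limma adjusted p = 0.0369), the platelet receptor gene GP9 by −6.43 (SE 0.57, adjusted p = 0.0497), and TUBB1 and VWF by −5.69 and −5.43. IL7R rose by 5.72 (SE 0.39, adjusted p = 0.0369), as did the interleukin antagonist gene IL1RN (5.11), RETN (4.87), MCEMP1 (4.78), the lipid regulator PPARG (4.74), the cytokine-induced CISH (4.52) and CD24 (4.52). The fetal globin gene HBG1 rose by 3.69 (adjusted p = 0.0369). CLEC1B was at least 106-fold lower and THBS1 at least 74.7-fold lower at day 9, while AGRP was at least 44.6-fold, BPI at least 39.6-fold, IGSF6 at least 26.0-fold and HK3 at least 25.3-fold higher. HP, which encodes the hemoglobin scavenger haptoglobin, was higher by 5.21 without being called (adjusted p = 0.0837).

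Among lineage lists, 34 of 39 monocyte and macrophage genes were higher in the control at day 9 and 5 lower (median 1.82), such as C1QC (4.19), CYBB (3.90), VCAN (3.83) and CD163 (3.62). In this list 0 genes were called by limma over all genes and 10 over the list alone, 9 higher and 1 lower, the lysozyme gene LYZ (−1.55), which was named after its value was seen. Neutrophil maturation had 18 of 20 higher (median 1.97), with the antimicrobial gene CAMP at least 7.49-fold higher (adjusted p = 0.0465), while LCN2 was at least 13.8-fold lower (adjusted p = 0.0393). Dendritic and MHC class II genes had 19 of 21 higher (median 1.13), including IL3RA (3.77), with CD1A at least 7.75-fold higher. The inflammatory list had 22 of 26 higher (median 1.49), with CCL2 at 3.27, and immediate early and heat shock genes 21 of 23 (median 0.85), with JUN at 3.14. Of the megakaryocyte and platelet genes 23 of 24 were lower (median −2.68), 7 called over all genes and 19 over the list alone. Of the stem and progenitor genes 32 of 35 were lower (median −1.52), with MYCN (at least 16.1-fold lower, adjusted p = 0.0369) and ANGPT1 (−4.04, adjusted p = 0.0415) called and 21 called over the list alone. CD34 was lower by −3.65 and SPINK2 by −4.01.

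Core histone genes were lower at day 9 in the control (median −0.70), and H2AC6 was at least 10.6-fold lower (adjusted p = 0.046). Below the random range too were the mast cell, basophil and eosinophil list (−0.39), with the IgE receptor gene FCER1A down by −2.55 (adjusted p = 0.0431), the interferon response (−0.33), oxidative phosphorylation (−0.27) and ribosomal protein genes (−0.26), with RPS2 down by −1.66 (adjusted p = 0.0497). The interferon median was 0.09 among the members detected on all 5 arrays. Unfolded protein and amino acid stress (0.47) was within the random range here but in only 1 of 8 other settings. Within the random range lay the SET1/MLL complex (−0.02), HOX and MEIS (−0.33), primary granule (0.29), erythroid (0.20), lymphoid (−0.03), G1/S (0.00), G2/M (0.14), CDK inhibitor and p53 target (0.09), MYC and ribosome biogenesis (0.11), cholesterol and lipid synthesis (0.32) and myeloid transcription factor (0.28) lists. MEIS1, a HOX cofactor of stem cells, was lower by −2.99 and SQLE, a cholesterol synthesis gene, fell by −2.50 (adjusted p = 0.0494). For G2/M, the CDK inhibitor list, MYC and ribosome biogenesis and cholesterol synthesis the mean was of the opposite sign or 0.00 (−0.09, −0.01, −0.16 and 0.00), as it was for the lymphoid (0.61) and SET1/MLL (0.07) lists.

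For the control at day 9 against day 0, limma called 75 genes, 39 higher and 36 lower, with 3342 at an unadjusted p under 0.05. These calls depend on the settings, with 0 at an offset of 50, 0 without a variance trend and 2 among genes detected on all 5 arrays. At least 2-fold differences numbered 2973 of 10807 detected genes, 1607 higher and 1366 lower. This compares 1 array with 1, and simulated data gave 624 unchanged genes past 2-fold per run, from a larger set of 11655 genes. The median of all genes differed by 0.09.

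At day 9 the knockdown culture with shRNA 2 had lower levels of macrophage and dendritic cell genes than the control and higher levels of granule genes. LGMN, a lysosomal protease of macrophages, was lower by −3.12, CES1 by −2.86, LILRB2 by −2.67, LY86 by −2.57, the lipid transfer gene PLTP by −2.50 and CYP27A1 by −2.45. The alpha defensin gene DEFA1 was higher by 3.15 (probes cannot separate it from near-identical paralogs), DEFA4 by 2.12, BPI by 2.07, SLPI by 2.25, SCGB3A1 by 2.58 and LRIG1 by 2.11. OLFM4, a marker of a neutrophil subset, was at least 3.06-fold higher and CEACAM6 was higher by 1.73. The fetal globin genes HBG1 and HBG2 were lower by −2.76 (SE 0.21 for HBG1).

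In the monocyte and macrophage list 31 of 39 members were lower at day 9 with knockdown and 8 higher (median −0.86), and 16 were at least 2-fold lower, among them CD163 (−2.25), APOE (−2.15) and GPNMB (−1.90). Dendritic and MHC class II genes had 17 of 21 lower (median −1.08), with CD1C at −1.75 and the interleukin receptor gene IL3RA at −1.64. The inflammatory list had 24 of 26 lower and 2 higher (median −0.39), including TNFAIP6 (−1.82), CCL20 (−1.33) and SOD2 (−1.28). Erythroid genes had 18 of 24 lower (median −0.42), with the hemoglobin chaperone AHSP at −2.07. In the mast cell, basophil and eosinophil list (median −0.20, 13 of 21 lower) the eosinophil granule genes PRG2 (−2.23) and CLC (−1.69) were lower, and PRG3 was at least 3.41-fold lower.

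Higher at day 9 with knockdown were primary granule genes (median 0.48, 15 of 17 higher, and 0.24 among the 13 detected on all 5 arrays) and neutrophil maturation genes (median 0.30). Of the latter 13 of 20 were higher, such as ANXA3 (1.35), but the gelatinase gene MMP9 was lower by −2.62, and 3 were at least 2-fold higher against 2 at least 2-fold lower. Small upward medians above the random range were found for core histones (0.38, 11 of 14 higher), the CDK inhibitor and p53 target list (0.20, with CDKN2A at 0.99), oxidative phosphorylation (0.19, 21 of 28 higher), G2/M (0.15, 31 of 41 higher) and ribosomal protein genes (0.12, 25 of 33 higher). Unfolded protein and amino acid stress was below it (−0.13, with SLC7A11 at −1.52), as it was in 5 of 8 other settings. For this comparison 12% of the 50 unchanged lists in simulated data lay outside the range, so small medians carry little weight. Within the range were stem and progenitor (0.05, mean −0.04), HOX and MEIS (−0.30, at percentile 2.53, and within the range in only 2 of 8 other settings), megakaryocyte and platelet (0.04), lymphoid (−0.08), G1/S (0.10), MYC and ribosome biogenesis (0.02, mean 0.00), interferon response (−0.09), immediate early and heat shock (0.01), cholesterol and lipid synthesis (0.11) and myeloid transcription factors (0.12). Even so, single members differed, such as DNTT (at least 2.96-fold lower), CD79B (−1.84), THBS1 (at least 1.75-fold higher), MX1 (−1.81), and the granulocyte factor CEBPE (0.94) against the monocyte and dendritic factor IRF8 (−1.39).

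For knockdown against control at day 9, limma called 0 genes, with 481 at an unadjusted p under 0.05 and a smallest adjusted p = 0.51. By size 546 of 10461 detected genes differed at least 2-fold, 130 higher and 416 lower, between 1 array and 1. Simulated data gave 627 unchanged genes past 2-fold per run, from a larger set of 11655 genes. The simulation used the spread between the 2 shRNAs and favoured neither direction. It therefore does not address the excess of lower over higher genes. In the self-test only 7.55% of genes changed by 2 were called here.

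**Figure D3:**
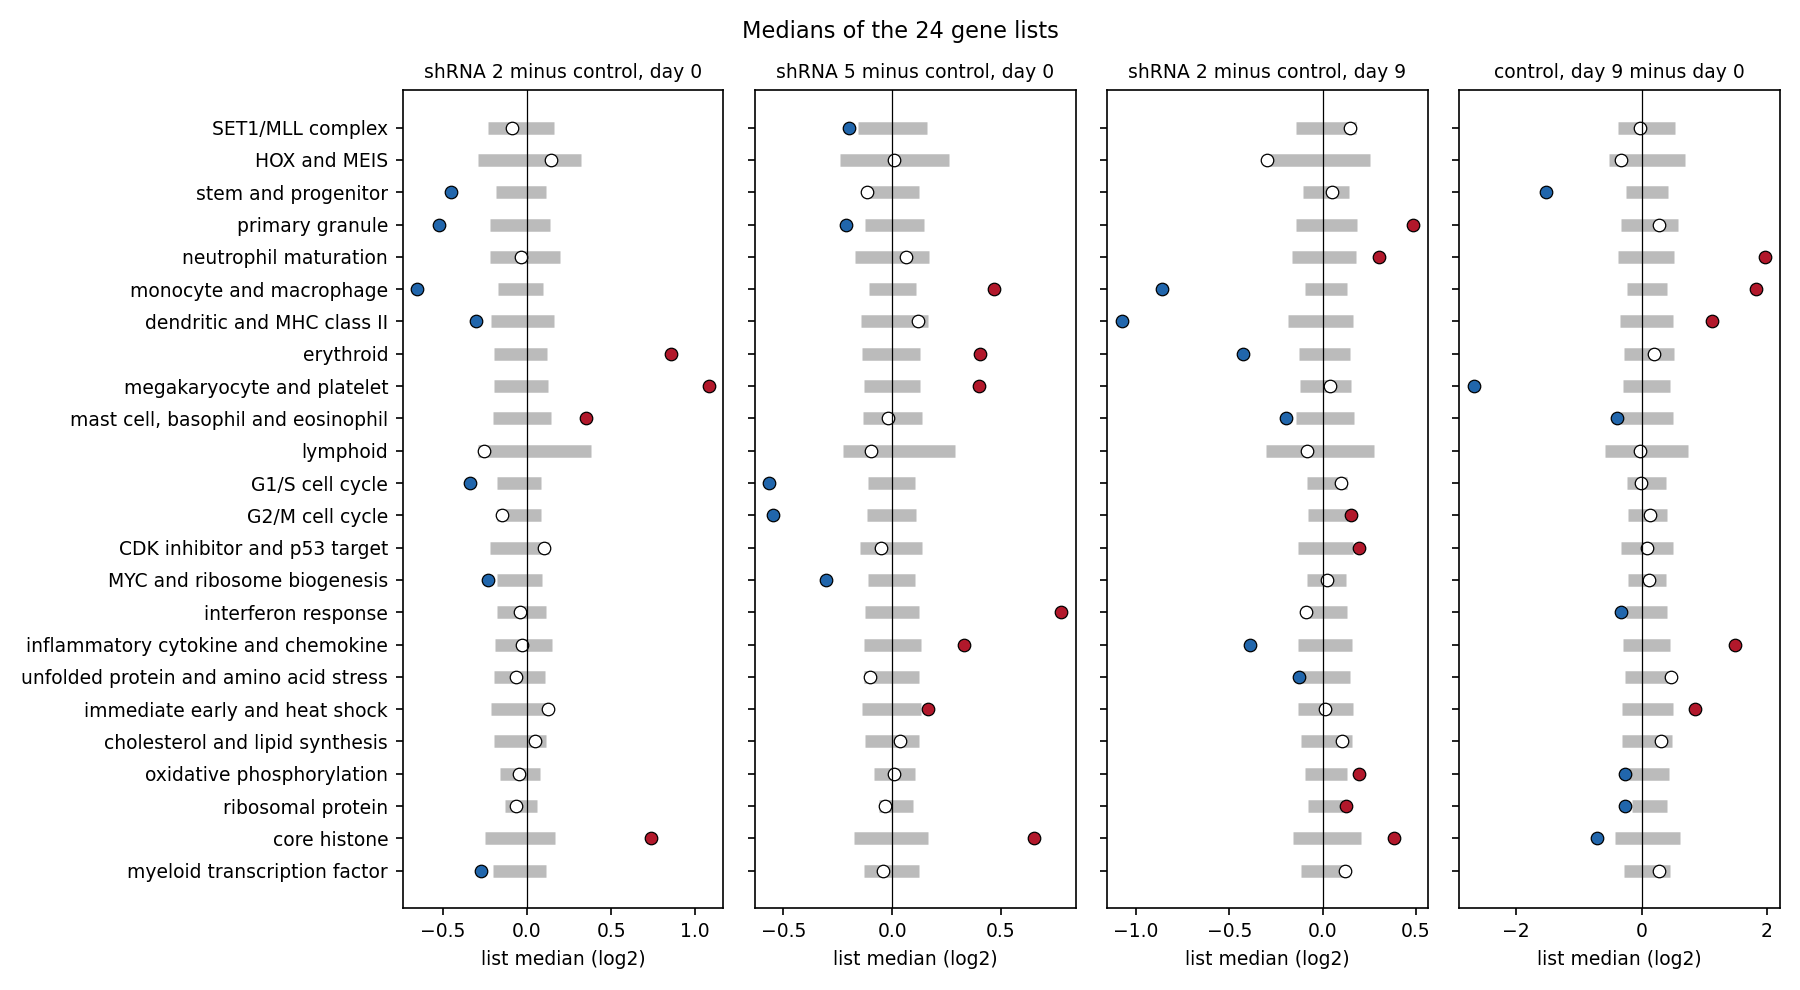
Median log2 difference of each of the 24 gene lists, for shRNA 2 and shRNA 5 at day 0, for shRNA 2 at day 9 and for the control over time. Grey bars give the range of random lists matched on expression, and filled points lie outside it.

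In knockdown cells too, granulocyte and monocyte genes were higher and platelet genes lower after 9 days, while red cell and primary granule genes took another course than in the control. CD24 rose by 6.32 (SE 0.28, limma adjusted p = 0.0117), HP by 6.04 (adjusted p = 0.042), IL7R by 5.23 (adjusted p = 0.0141), MCEMP1 by 5.08 and the protease inhibitor gene SLPI by 5.06, while CLEC1B fell by −6.94, GP9 by −6.90, VWF by −6.42 and TUBB1 by −6.32. DEFA1 was at least 246-fold and BPI at least 196-fold higher. The list medians at day 9 against day 0 were 2.03 for neutrophil maturation, 1.84 for primary granule, 1.00 for monocyte and macrophage, 0.63 for dendritic and MHC class II, −0.76 for erythroid, −1.29 for core histone, −1.50 for stem and progenitor and −3.99 for megakaryocyte and platelet genes. Within the shRNA 2 culture, the median change of the list was 103% of that in the control for neutrophil maturation, 84.9% for stem and progenitor, 80.3% for monocyte and macrophage, 63.7% for dendritic and MHC class II, 50.7% for inflammatory and 170% for megakaryocyte and platelet genes. Erythroid genes changed by −1.11 there against 0.20 in the control, and primary granule genes by 1.91 against 0.29. The shares depend on unequal levels at day 0, so they do not measure how far the cells differentiated. For shRNA 2 against the control, megakaryocyte and platelet medians were 1.08 at day 0 and 0.04 at day 9. They were −0.45 and 0.05 for stem and progenitor genes, and −0.65 and −0.86 for monocyte and macrophage genes. These differences between the courses were not tested for lists. Here limma called 926 genes, 431 higher and 495 lower, with 4005 at an unadjusted p under 0.05. The fit has 2 arrays at day 0 in this contrast, with different shRNAs, and shRNA 2 alone at day 9. Its count is therefore not comparable with the 75 in the control, and the shRNA is mixed with the day.

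**Figure D4:**
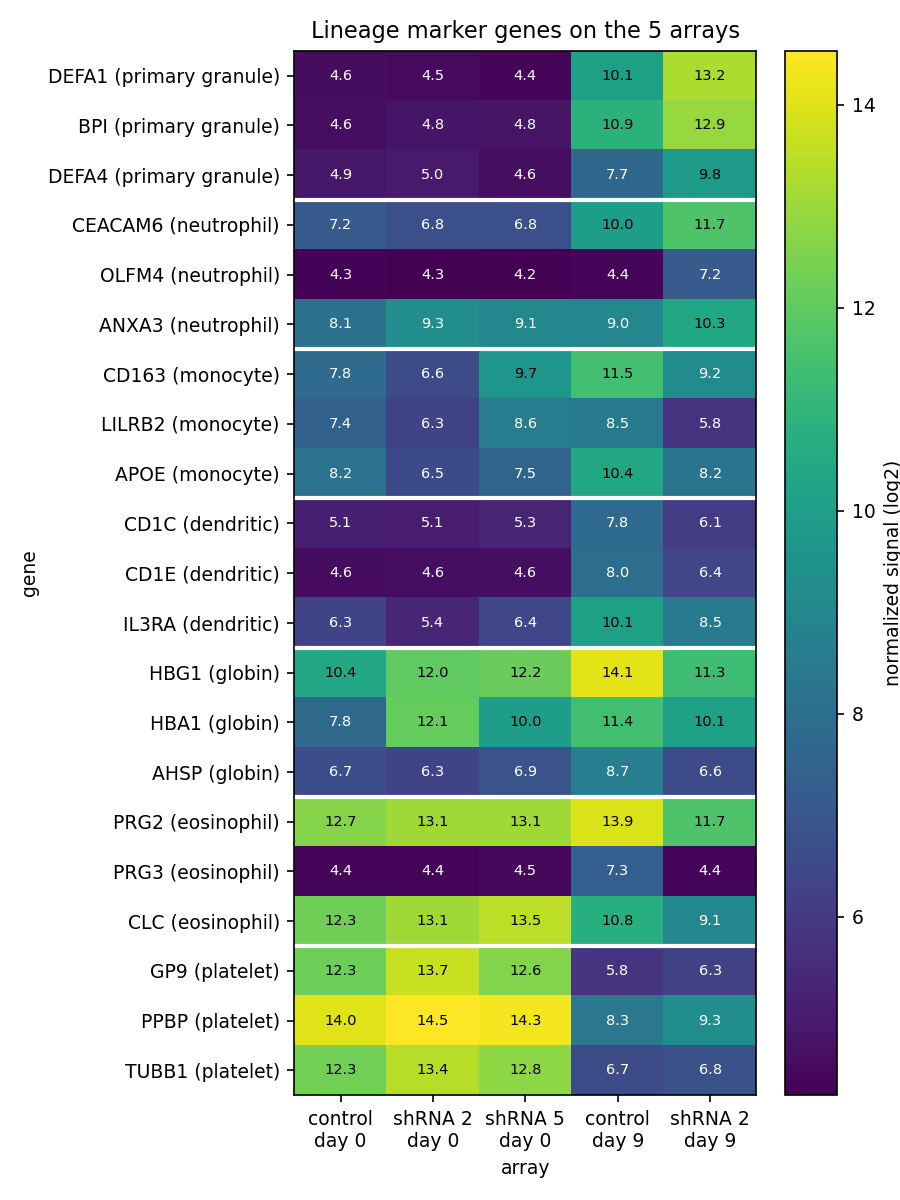
Normalized log2 signal of marker genes for granulocyte, monocyte, dendritic, red cell, eosinophil and platelet lineages on each of the 5 arrays. Each cell of the map gives the value of 1 gene on 1 array.

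The effect of knockdown differed between the days most for the globin genes. The fit sets the mean of shRNA 2 and shRNA 5 at day 0 against shRNA 2 alone at day 9, so the shRNA is mixed with the day. HBG1 went from higher at day 0 to lower at day 9, an interaction of −4.46 (SE 0.28, limma adjusted p = 0.347), with HBG2 at −4.39, HBA2 at −4.83, HBA1 at −4.50 and the embryonic HBE1 at −4.73. On the other side, the proline oxidase gene PRODH was at 2.33, SLPI at 2.32, LRIG1 at 2.24 and CEACAM6 at 2.17. For the interaction, limma called 0 genes, with 355 at an unadjusted p under 0.05 and a smallest adjusted p = 0.347. Across genes the day 0 and day 9 knockdown differences had a correlation of r = 0.0482 (0.123 for shRNA 2 alone and −0.0655 for shRNA 5), and genes are not independent replicates.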

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

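The tests of the progenitor share, of chance deviation of the control, of slower differentiation and of a difference carried since day 0 were chosen only after the results were seen. The tests of normalization were written down beforehand.

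A pair of lists went one way at day 0 with both shRNAs and the opposite way at day 9 with shRNA 2. Primary granule genes had medians of −0.52 with shRNA 2 and −0.21 with shRNA 5 at day 0 and 0.48 at day 9, and the median over its members of each gene's knockdown difference at day 9 minus its mean difference at day 0 was 1.29. Erythroid genes had medians of 0.85 and 0.40 at day 0 and −0.42 at day 9, and the same median over members was −0.78. A median of differences is not the difference of the medians. These differences between the days were not tested.

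Megakaryocyte and erythroid genes were higher at day 0 with both shRNAs, and under other normalizations and background treatments their medians were at least 0.36 and 0.34, which argues against normalization. A smaller share of progenitors that raised the markers of every other cell type alike would raise monocyte genes too. With shRNA 2, however, the monocyte and macrophage median was −0.65 while the megakaryocyte and platelet median was 1.08. With shRNA 5 monocyte genes were higher too (0.47), but the rise was not alike across lists there either. Neutrophil maturation (0.06) and mast cell, basophil and eosinophil genes (−0.02) lay within the random range and primary granule genes (−0.21) below it. The stem and progenitor median with shRNA 5 (−0.11) was within the range. Changes in the shares of cells that are not alike across cell types were not tested. Each shRNA was measured on 1 array. Of 100 simulations with unchanged cells 97 reached the observed 100 higher genes at the unmoderated spread and 0 at the moderated spread. However, the unmoderated spread also gave 117 lower genes where 7 were observed, and a covariance of 0.126 against 0.0759 observed, while the moderated spread gave 0.0746. A deviation of the single day 0 control culture in these genes still cannot be told apart from an effect of knockdown, as no second control was measured at day 0.

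Monocyte, dendritic and inflammatory genes were lower at day 9 with shRNA 2. The monocyte and macrophage median was −0.78 or lower under each of the 4 other treatments of the signals, which argues against normalization. Slower differentiation along every myeloid lineage could lower neutrophil maturation genes too. Their median was instead higher by 0.30, at percentile 99.93 of random lists, with 13 of 20 members higher and 7 lower. The median cannot decide this, since 3 members were at least 2-fold higher and 2 at least 2-fold lower, among them MMP9 (−2.62). Primary granule genes were higher too (0.48), and the list was not split by stage of maturation. A difference that this culture carried since day 0 is a candidate explanation for the monocyte and dendritic genes. Across the members of the monocyte list the shRNA 2 differences at day 0 and day 9 had r = 0.346, against r = −0.233 for shRNA 5 at day 0. For dendritic and MHC class II genes r was 0.588 against 0.0943. For inflammatory genes r was 0.269 against 0.228, and their shRNA 2 median at day 0 was −0.03, within the random range, so no such difference was seen there. Such an r leaves out the shift of a list as a whole. Primary granule genes had r = 0.654 with shRNA 2, although their median changed sign between the days. The r values therefore cannot decide whether a difference was carried. By direction, 25 of 39 monocyte genes were lower with shRNA 2 at both days and 1 was higher at both. Of the 21 dendritic and MHC class II genes, 13 were lower and 3 higher at both days. Members are not independent replicates. An effect of DPY30 knockdown itself on the monocytic lineage also stays open, as shRNA 5 was not measured at day 9.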

How the results depend on the processing

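The fit of day blocked on the shRNA was chosen only after the results were seen. Of 134 comparisons of a main result with an alternative, 101 stayed close and 33 moved. The close ones include every comparison in which neither setting called a gene. For the correlation of the day 0 and day 9 differences, close meant within the spread between the shRNAs (0.133). The values from leaving out each array, −0.0655 and 0.123, set that spread themselves. They counted as close despite their opposite signs, so the tally overstates how stable the results are. For list medians 947 of 1008 kept their side of the random range, 22 moved inside it, 33 moved outside it, 1 moved outside it with the opposite sign (monocyte genes at day 0, 0.47 with shRNA 5 alone), and 5 that lay outside it changed sign. Medians near 0 within it changed sign more often, such as cholesterol synthesis in the control (−0.04 to 0.46). For named genes 3227 of 3657 values stayed within the spread and 430 moved, with 0 sign changes among called values.

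The 75 genes called for the control at day 9 against day 0 became 128 with median scaling, 0 with an offset of 50, 21 with the authors' values, 2 among genes detected on all 5 arrays, 1228 with no detection filter, 27 with the mean of probes, 0 for eBayes without a trend, 49 with robust eBayes and 4406 in the additive fit. The 926 for knockdown became 1463 with median scaling, 2006 with no filter and 532 without a trend. With no filter 10 genes were called for knockdown at day 9 and 3 for the interaction, and 0 for knockdown at day 0 (limma, 691 at an unadjusted p under 0.05). Without the filter the fit took in 42568 features, unnamed probes included, with calls counted among named genes. The prior degrees of freedom were 7.95 in place of 3.32. At a detection p under 0.05 the same 13430 named genes were fitted without the unnamed probes. The calls for knockdown at day 9 and for the interaction were not made there. They therefore came with the unnamed probes in the fit, and not with more named genes. For the other settings the cause was not tested. Of the calls in the control 76.2% were higher with the authors' values and 63.8% by quantiles without background correction, against 52.0%.

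Genes at least 2-fold different at day 0 (107) and day 9 (546) became 43 and 266 by quantiles without background correction, 50 and 302 with an offset of 50, 43 and 268 with the authors' values, and 47 and 290 among genes detected on all arrays. An offset and an uncorrected background shrink folds by construction. A 1.5-fold threshold gave 473, 1504 and, for the control over time, 5568, and a 3-fold threshold 23, 143 and 1131.

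Leaving out each day 0 knockdown array gave 267 to 639 genes, since only 1 shRNA then has to pass, and a ratio of the SD of the day 9 minus day 0 differences in knockdown to that in the control of 1.03 to 1.13. It moved the day 0 median of the interferon list from −0.04 to 0.78 and of the inflammatory list from −0.03 to 0.33. No residual degree of freedom remains, so this gives no test. The 14 lists called by camera became 0 with an estimated correlation, which rests on 1 residual degree of freedom. The interferon median in the control over time was 0.09 in place of −0.33 among members detected on all 5 arrays. The day 0 lymphoid median was 0.01 in place of −0.26 with no filter and with a detection p under 0.05, where the list has 16 members and not 8. The median shift of all genes in the control was 0.12 with the authors' values, against 0.09.

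The labels give no replicate numbers that pair the arrays. A fit with 1 common day effect, blocked on the shRNA, called 4573 genes with limma, among them 73 of the 75. It has 7.02 prior degrees of freedom and takes the day effect to be the same in control and knockdown. Between 10029 and 10655 of the genes were detected per array, and genes near background have compressed folds.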

Other observations

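The comparison of the shRNAs with each other, the naming of genes called without a detection filter and the test of more monocytes in the shRNA 5 culture were chosen only after the results were seen. At day 0 the 2 knockdown cultures differed from each other in macrophage genes and in some platelet and red cell genes, which was not tested. Macrophage genes were higher with shRNA 5 than with shRNA 2, such as RNASE1 (3.64), CCL8 (3.57), the complement gene C1QB (2.98) and TGFBI (2.73), while the smooth muscle and platelet gene KCNMB1 (−3.28), the embryonic globin gene HBE1 (−3.10), LRRC32 (−2.59) and the erythroid gene HEMGN (−2.50) were lower. Of 39 monocyte and macrophage genes, 26 were lower with shRNA 2 and higher with shRNA 5. Megakaryocyte and platelet genes mostly kept their direction, with 2 of 24 opposite between the shRNAs, and their median of shRNA 5 minus shRNA 2 was −0.57. For erythroid genes 7 of 24 were opposite and that median was −0.56. At least 2-fold differences between the shRNAs numbered 629, beside 639 between shRNA 2 and the control and 267 between shRNA 5 and the control.

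Some genes differed at least 2-fold with shRNA 2 at both days. Of the 171 lower at day 0, 53 were lower at day 9 as well, where independent lists would share 6.24, and of the 468 higher at day 0, 20 were higher at day 9, against 5.30. For shRNA 5 at day 0 and shRNA 2 at day 9 the overlaps were 12 lower and 12 higher, against 2.12 and 2.28.

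Without a detection filter, limma called 10 genes for knockdown at day 9. Lower were the fetal globin genes HBG1 and HBG2 (−2.76, adjusted p = 0.0101), the eosinophil granule genes PRG2 (−2.23, adjusted p = 0.0101) and PRG3 (at least 3.41-fold), and the acute phase gene ORM1 (at least 4.66-fold). Higher were the water channel gene AQP2 (at least 6.51-fold), OLFM4 (at least 3.06-fold), SPINK6 (at least 1.66-fold) and near-identical alpha defensin genes, of which DEFA1B was at 3.28. For the interaction the 3 called were HBG1 (−4.46, adjusted p = 0.00283), HBG2 (−4.39) and PRG2 (−2.64, adjusted p = 0.0255). Over the filtered genes none of these passed. Nor did any pass when the same named genes were fitted without the unnamed probes. These calls therefore depend on the unnamed probes in the fit.

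Interferon genes were higher at day 0 with shRNA 5 and not with shRNA 2. More monocytes in the shRNA 5 culture could move interferon genes along with monocyte genes. With shRNA 2, where monocyte genes were lower, the interferon median was −0.04, at percentile 48.36 of random lists. That value comes from the other culture, so it cannot decide whether monocytes raised interferon genes with shRNA 5. Under the 4 other treatments of the signals the median difference between shRNA 5 and shRNA 2 was at least 0.66, which argues against normalization. A response of the shRNA 5 culture to its virus or hairpin could also raise these genes, and it was not tested.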
